A study of Mus musculus with 7 samples.

How the data were processed

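RNA was measured in atrioventricular canals, the narrow part of the embryonic heart tube between atrium and ventricle where the valves begin to form, dissected from outbred NMRI mouse embryos. Per the labels, the embryos had 18 to 23 somites, which the labels give as embryonic day 9.0 to 9.25, while the sample titles read day 9.5. Each library came from a pool of 4 canals, and pools were matched on somite stage and sex ratio. The Hand2 null allele lacks the whole coding part of the gene, deleted in the germline. Per the labels, 4 pools were planned per genotype, and 1 wild-type pool was not sequenced because of its RNA quality. The other 7 had RNA integrity numbers of at least 8.5 and 30 to 60 ng of total RNA. That left 4 null and 3 wild-type pools, and each pool is 1 replicate. Ribosomal RNA was depleted, cDNA was made with a low-input kit and amplified for 8 cycles of PCR, and single reads of 50 nt were sequenced without strand information, per the labels' protocols. Without strand, reads from a gene and from an overlapping antisense gene cannot be told apart, and after PCR without molecular identifiers reads are not independent molecules.

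The deposited files hold counts: whole-number read counts per gene for 23284 gene symbols, 1 file per library. Per the submitters' processing notes, TopHat2 2.0.13, HTSeq and SAMtools were used with the mouse build mm9. The gene annotation and the counting options are not given in the sources used here. Each deposited file also ends with 5 summary lines of the counter, which were left out of library sizes and tests. Reads in no gene were 7.31% to 14.21% of all counted reads, reads in more than 1 gene 1.46% to 1.69%, and reads that aligned to several places 9.08% to 11.64% in null and 12.22% to 13.81% in wild-type libraries. The last group is not in the gene counts, so genes with near-identical copies (ribosomal proteins, histones, Atp5g1) are uncertain. The reads assigned to genes numbered 27905601 to 44860753 per library. A count of 3 reads corresponded to 0.0669 to 0.1075 counts-per-million units (CPM), which was taken as the floor and covers counting error only. Reference tables of build GRCm38 were used for names, gene length, GC content and the order of genes along the chromosome. They matched 20882 symbols directly and 1942 through older names, and 460 did not match. No coordinates of that build are given, because the counts were made on mm9.

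The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM normalization, the default filter on low counts (minimum count 10) and genotype as the only term, over all 7 libraries with 5 residual degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Standard errors (SE) are the log2 fold change divided by the square root of F. Gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01 between genes, adjusted over 31 lists. Camera with an estimated correlation and fry were alternatives. Each list also has a score, the mean log2 CPM of its tested members, compared by a two-sided exact permutation test over the 35 splits of 7 libraries into 4 and 3, for which 0.0286 is the smallest p possible. These score tests were added after the data had been seen. Genes near Hand2 were compared with the rest by a two-sided Fisher's exact test. The groups, the main tests, the lists, the rule for naming genes and all alternatives except those said to be chosen later were fixed before the data were examined.

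The rule names Hand2, a preset group of valve and heart genes, the 10 genes with the largest fold change in each direction among called genes without overlap between groups and with at least 10 CPM in the higher group, the 5 genes with the smallest p in each direction, up to 4 called members of each list (or, where none was called, the 2 most abundant), and called genes within 1 Mb of Hand2. Small RNAs and predicted genes were skipped in the ranked parts. It named 117 genes, of which 3 are not reported here. The preset antisense neighbour of Hand2 was not analysed here. Genes outside it are said to be so where they appear. Of the list members, 7 had no row under their symbols. Some genes stand in several lists, such as Ero1l in those of hypoxia and of unfolded protein stress, so list results are not independent. The ribosomal list was built from symbol prefixes and so takes in Rps19bp1, which is not a ribosomal protein.

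The scripts were tested on counts simulated for the real genes, library sizes and dispersions, with 200 genes changed in the comparison of null and wild-type libraries. Over 14104 tested genes, 19.4% of genes changed 1.5-fold were recovered, 71.6% of those changed 2-fold and 98.5% of those changed 4-fold, all among genes with a mean of at least 50 reads. Of 134 calls, 8 were false. A simulated list of 30 genes raised 1.5-fold was called and none of 20 unchanged lists was, although simulated genes vary independently and real ones do not. Alternatives were other scaling factors, DESeq2 1.42.0, limma-voom, a robust fit, other filters, thresholds and windows, a replicate block, offsets for GC content (known for 98.8% of tested genes) and, chosen after seeing the data, transcript length, covariates for blood and for Y-linked transcripts, abundant transcripts left out, and each library left out in turn. Within each genotype, replicate pairs differed by more than sampling noise (chi-square per degree of freedom 26.7 to 137.4), so no library was counted as a copy of another.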

Results

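Expression was measured in the atrioventricular canal of Hand2 null embryos (4 pools) and wild-type embryos (3 pools) at the stage when endocardial cells begin to form valve mesenchyme. HAND2 is a basic helix-loop-helix transcription factor, and the series title places the comparison in cardiac valve development. The null libraries 1 to 4 held 37340143, 32846751, 28667561 and 38938029 reads in genes, and the wild-type libraries 2 to 4 held 44860753, 28909205 and 27905601.

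Hand2 itself was counted 7, 26, 10 and 14 times in null replicates 1 to 4, against 2123, 1224 and 1194 times in wild-type replicates 2 to 4. This was 0.413 ± 0.236 CPM (SD, n = 4) against 44.5 ± 2.43 CPM (SD, n = 3), a log2 fold change of -6.74 (SE 0.301, edgeR adjusted p = 5.72e-07). All 7 libraries thus matched their genotype labels. Hand2 lies on chromosome 8 and has 2 annotated exons in GRCm38, and the deletion covers its coding part, so reads from untranslated sequence can remain in null tissue.

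The null canals expressed more of the transcripts of glycolysis and low oxygen and of part of the endothelial programme, and less of several mesenchymal transcription factors, while matrix genes went both ways. Of 14290 genes tested, 587 were higher and 305 lower in the null, of which 324 and 88 changed at least 2-fold. The highest folds among abundant genes included the mitochondrial protein gene Ndufa4l2 (log2 fold change 3.88, SE 0.301), the protease inhibitor A2m (3.22, SE 0.387), the secreted glycoprotein Stc2 (3.14, SE 0.25), the enolase Eno2 (2.92, SE 0.274), the adaptor gene Lims2 (2.85, SE 0.362) and the noncoding RNA Neat1 (2.79, SE 0.527). The smallest p-values among higher genes also belonged to Krt19, an epithelial keratin, at 471 ± 76.0 against 88.7 ± 1.13 CPM, to Sncb (7.45 ± 2.20 against 0.202 ± 0.0207 CPM) and to the potassium channel subunit Kcne3 (8.29 ± 0.969 against 0.343 ± 0.175 CPM; SD, n = 4 and 3). After Hand2, the chemokine Ccl2 fell most among abundant genes, from 12.9 ± 3.79 to 0.342 ± 0.255 CPM (log2 fold change -5.21, SE 0.416, adjusted p = 5.53e-05). Also lower were Cthrc1 (-2.86, SE 0.487), the neuronal tubulin Tubb3 (-2.20, SE 0.323), Plac1 (-1.61, SE 0.177) and Olfml3 (-1.57, SE 0.187). Without wild-type replicate 4 the values of Cthrc1 and Tubb3 were -1.80 (adjusted p = 0.00754) and -1.58 (0.00267), and without null replicate 2 those of Neat1 and Ccl2 were 2.16 and -5.86.

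The counts changed when single libraries were left out. Leaving out a library also removes a replicate from the test, so a lost call does not by itself show that the library made it. Without wild-type replicate 2 the log2 fold change of Fzd1 was 1.39, against 1.38 with all libraries, while that of Crabp1 was -0.71 against -1.32. The numbers higher and lower were 210 and 46 without wild-type replicate 2, 246 and 68 without wild-type replicate 3, 284 and 90 without null replicate 1, 389 and 150 without null replicate 2, and 946 and 652 without null replicate 3. Of 97 called genes named by the rule, 52 kept their call with any library left out. The other 45 lost it at least once, 41 of them without wild-type replicate 2, 30 without wild-type replicate 3, 27 without null replicate 1, 18 without null replicate 2, 15 without wild-type replicate 4, 8 without null replicate 4 and 4 without null replicate 3. These included Atp5g1, Ccnd2, Crabp1, Cycs, Dll4, Efnb3, Epha3, Flt1, Fzd1, Gpm6a, Hey1, Hhex, Hist3h2ba, Hopx, Hpgd, Irx4, Irx5, Isl1, Kcne1, Klf1, Krt8, Lyz2, Mfng, Mrc1, Msx1, Myh7, Myl2, Nebl, Notch4, Osr1, Pcna, Polk, Postn, Rpl34, Rps19bp1, Rps27l, Sesn2, Sfrp5, Snai1, Sox9, Tyms and Vegfc. Genotypes separated on the first principal component, which held 38.3% of the variance. Null replicate 2 had the highest share of reads in no gene (14.21%) and wild-type replicate 4 the highest share of haemoglobin reads (2.18%), and without both libraries the counts were 298 and 123.

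**Figure D1:**
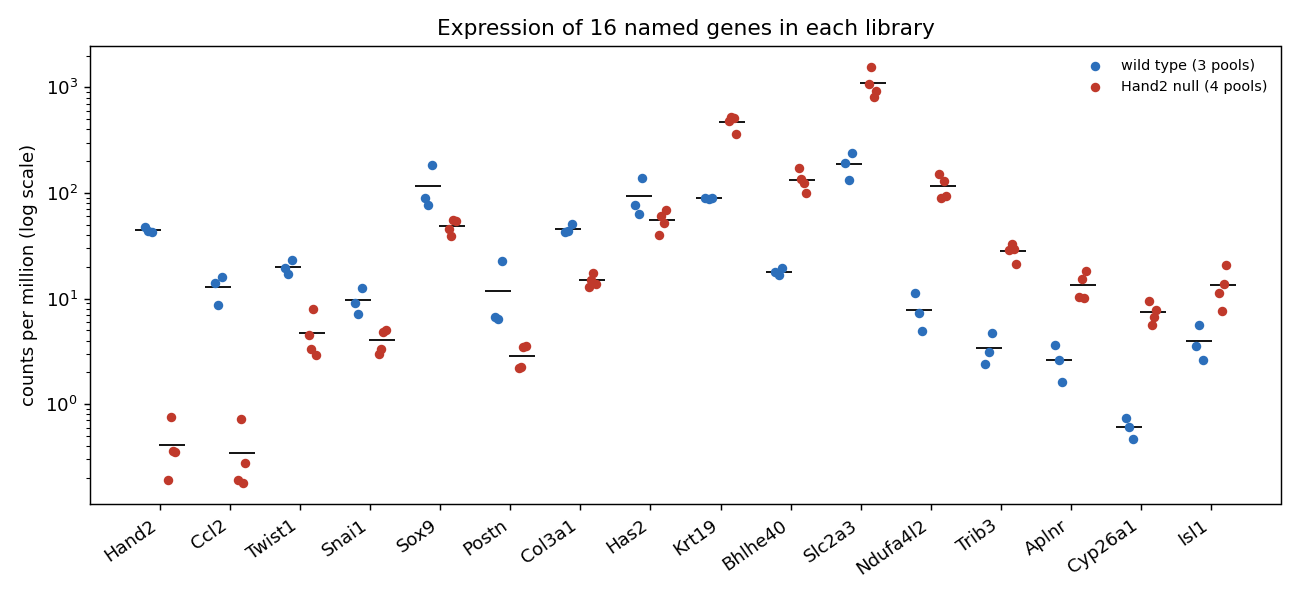
Expression of 16 named genes in CPM (log axis), with 1 point per library, wild type in blue (n = 3) and Hand2 null in red (n = 4), and a bar at each mean. Hand2 stood at 0.413 CPM in the null against 44.5 CPM in wild type, and the points of Has2 overlapped.

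Genes of cushion mesenchyme and of the endothelial-to-mesenchymal transition (EndMT), the step by which endocardial cells become valve mesenchyme, came lower where they were called. Of 29 list members, 7 fell and none rose (10 lower and 2 higher when adjusted over the list alone). They were the transcription factors Twist1 (log2 fold change -2.10, SE 0.301, adjusted p = 0.00194), Snai1 (-1.25, SE 0.258, adjusted p = 0.0157), Sox9 (-1.27, SE 0.258, adjusted p = 0.0145), Msx1 (-1.46, SE 0.391, adjusted p = 0.0477) and Twist2, with the matrix genes Postn (-2.04, SE 0.413, adjusted p = 0.0141) and Hapln1. Twist2 and Hapln1 lay outside the naming rule and were named after their values were seen. Twist1 was 4.68 ± 2.29 CPM in the null and 19.9 ± 3.01 CPM in wild type. The list as a whole was not called (camera adjusted p = 0.0754, median -0.10), and its score of 4.68 ± 0.18 against 5.05 ± 0.28 did not pass the threshold (exact permutation p = 0.1143, n = 4 and 3). Wild-type replicate 4, richest in haemoglobin, had the highest list score (5.329, against 4.771 and 5.06 in the other wild-type libraries) and the most Sox9 (185 CPM, against 77.7 and 90.0). The number of lower members was 1 without null replicate 1, 4 without null replicate 2, 3 without wild-type replicate 2, 3 without wild-type replicate 4, and 1 without null replicate 2 and wild-type replicate 4 together. The list was called lower without null replicate 3 (median -0.199, adjusted p = 0.0473), null replicate 4 (-0.135, 0.049), wild-type replicate 2 (-0.195, 0.0489) or wild-type replicate 3 (-0.176, 0.00298). Its median was -0.051 without null replicate 2 and -0.044 without wild-type replicate 4. It was also called lower with no filter on low counts (0.0488) and the Y-linked covariate (0.00399). Mixed fry asks whether members change in either direction, without comparing the list with other genes. It called the EndMT list (adjusted p = 9.52e-05) among 18 lists that camera did not call, so a call by mixed fry does not set a list apart. Snai1, Sox9 and Postn lost their calls without null replicate 1 (adjusted p = 0.0543, 0.0538 and 0.0541), and Snai1 also without wild-type replicate 2 (0.0643) or wild-type replicate 4 (0.0542). Postn was -1.19 (0.0384) without wild-type replicate 4. Msx1 lost its call in 5 of the 7 fits, without null replicate 1 (0.114), 2 (0.114) or 4 (0.0515), or wild-type replicate 2 (0.148) or 4 (0.159).

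Several preset valve and heart genes did not pass the threshold. The hyaluronan synthase Has2 was 55.3 ± 12.3 CPM in the null and 92.9 ± 40.9 CPM in wild type (log2 fold change -0.75, SE 0.256, adjusted p = 0.102), and its log2 fold change was -0.34 without wild-type replicate 4. Values for the canal genes were -0.64 (SE 0.301) for Tbx2, 0.40 (SE 0.23) for Tbx3, -0.25 (SE 0.234) for Bmp2, -0.19 (SE 0.239) for Msx2 and 0.21 (SE 0.185) for Tgfb2. The chamber peptide Nppa had 0.51 (SE 0.258), the endocardial genes Nfatc1 and Notch1 had -0.09 (SE 0.161) and -0.23 (SE 0.163), and the growth factor Vegfa had 0.94 (SE 0.323, adjusted p = 0.101). The cardiac factors Gata4, Hand1, Nkx2-5 and Tbx20 had -0.21, -0.10, 0.32 and 0.02, with SE of 0.23, 0.246, 0.232 and 0.134. With 1 library left out, Tbx2 passed without null replicate 3 (-0.996, adjusted p = 0.0219), Vegfa without null replicate 4 (1.18, 0.00936) and Tbx3 without wild-type replicate 4 (0.78, 0.0333).

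Transcripts of glycolysis and the hypoxia response rose together. Of 34 list members, 26 rose and none fell (33 higher when adjusted over the list alone), with a median log2 fold change of 1.10. The glucose transporter Slc2a3 rose from 189 ± 53.3 to 1097 ± 336 CPM (log2 fold change 2.54, SE 0.261, adjusted p = 0.000297). The transcription factor Bhlhe40 rose by 2.90 (SE 0.191, adjusted p = 2.04e-05), Ndrg1 by 3.04 (SE 0.324), the oxygen sensor Egln3 by 2.97 (SE 0.356) and the collagen prolyl hydroxylase P4ha2 by 2.02 (SE 0.185). The list was called by camera (adjusted p = 1.08e-22), but not with an estimated correlation (adjusted p = 0.246 with an estimated correlation). Its score was 8.12 ± 0.24 in the null and 6.83 ± 0.04 in wild type, without overlap (exact permutation p = 0.0286, n = 4 and 3, the smallest possible, 0.089 adjusted over the 31 lists). Scores of other lists had the same p without overlap. Among them were the axon guidance, retinoic acid and p53 lists, which camera did not call. It had 16 members higher without wild-type replicate 2, and 18 without wild-type replicate 3.

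Of 23 immediate early and heat shock genes, 8 rose and none fell (11 higher when adjusted over the list alone), among them Ier3 (2.62, SE 0.243), Nr4a1 (1.17, SE 0.184), Zfp36 (0.91, SE 0.146) and Fos (1.00, SE 0.167). The camera adjusted p was 6.39e-05, against an adjusted p of 0.381 with an estimated correlation. Of 26 genes of the unfolded protein and amino acid stress response, 7 rose and none fell (10 higher when adjusted over the list alone), including the pseudokinase Trib3 (3.06, SE 0.257), the glutathione-degrading enzyme Chac1 (2.77, SE 0.36), the oxidase Ero1l (1.57, SE 0.171) and the mitochondrial enzyme Shmt2 (0.78, SE 0.128). Its camera adjusted p was 0.000484, against an adjusted p of 0.246 with an estimated correlation. The p53 and apoptosis list was not called (adjusted p = 0.0756), with 3 of 27 members higher (4 when adjusted over the list alone), which were Plk2 (1.38), Sesn2 (1.22) and Polk (0.76). It was called higher without null replicate 1 (adjusted p = 0.0468), null replicate 4 (0.0425) or wild-type replicate 2 (0.048), and with the Y-linked covariate (0.046).

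**Figure D2:**
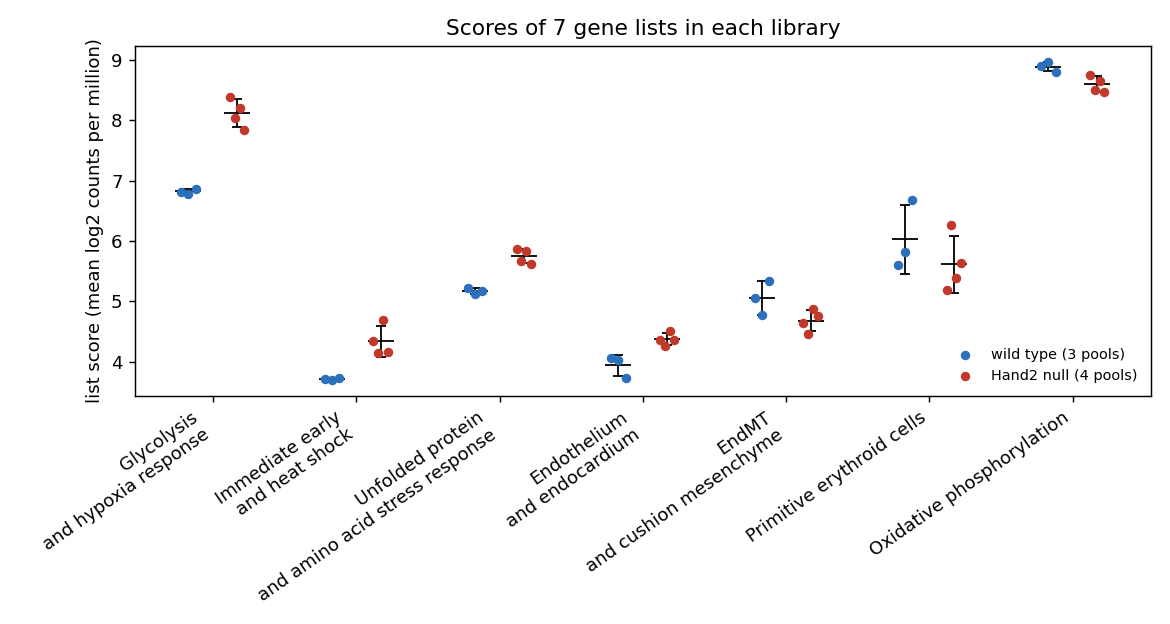
Scores of 7 gene lists (mean log2 CPM of tested members) with 1 point per library, wild type in blue (n = 3) and Hand2 null in red (n = 4), and bars for mean and SD. The glycolysis and hypoxia score was 8.12 in the null and 6.83 in wild type without overlap, while the points of the EndMT and erythroid lists overlapped.

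Of 45 endothelial and endocardial genes, 15 rose and 1 fell (21 higher and 4 lower when adjusted over the list alone). Aplnr, the apelin receptor, rose by 2.35 (SE 0.314), Vwf by 1.80 (SE 0.265), the receptor kinase Tie1 by 1.10 (SE 0.168) and the junction protein gene Esam by 1.11 (SE 0.179). The member that fell was the flow-responsive factor Klf2 (-1.14, SE 0.249), named after its value was seen. The camera adjusted p was 0.000351, against an adjusted p of 0.477 with an estimated correlation, and 9 members were higher without wild-type replicate 2, as without null replicate 2 and wild-type replicate 4 together. Of 25 Notch genes, 4 rose and none fell (5 when adjusted over the list alone), namely the ligand Dll4 (1.51), Mfng (1.55), Notch4 (1.41) and the target Hey1 (1.10). All 4 lost their calls without wild-type replicate 2 (edgeR adjusted p = 0.0676 to 0.183) and without null replicate 1 (0.0686 to 0.105). Notch4 lost its call with any 1 library left out. Mfng lost it also without null replicate 2 or 4 or wild-type replicate 3 or 4, and Hey1 also without wild-type replicate 3 or 4. The Notch list was not called by camera (adjusted p = 0.737), though mixed fry called it (0.000709).

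None of the other signalling lists was called by the main test. Mixed fry called all 5 of these lists (adjusted p = 6.81e-08 to 8.67e-06). The FGF, EGF and VEGF list was called higher with RLE (adjusted p = 0.0484) or upper-quartile scaling (0.0462), the GC-content offset (0.0414), the Y-linked covariate (0.0193) and directional fry (0.0486). It was also called without any 1 library except null replicate 3 or wild-type replicate 4 (0.0238 to 0.0385). The retinoic acid list was called higher with no filter on low counts (0.0488), a stricter filter (0.0367) and the Y-linked covariate (0.042). It was called as well without null replicate 1 (0.0468), 2 (0.0226) or 4 (0.0246), or wild-type replicate 2 (0.0159). Of 43 BMP and TGF-beta genes, 2 rose (also 2 when adjusted over the list alone, list adjusted p = 0.316), among them the receptor Acvrl1 (2.58, SE 0.313). Of 32 WNT genes, 3 rose and 2 fell (5 and 3 when adjusted over the list alone, list adjusted p = 0.665), among them Dkk3 (1.37) and Fzd1 (1.38) higher and Wnt4 (-1.68) and Sfrp5 (-0.96) lower. Of 33 FGF, EGF and VEGF genes, 6 rose and 1 fell (10 and 1 when adjusted over the list alone, list adjusted p = 0.0539), with Pdgfb (2.02), Dusp6 (0.84), Kdr (0.94) and Flt1 (0.94) higher. Of 22 genes of the retinoic acid pathway, 4 rose and 1 fell (6 and 1 when adjusted over the list alone, list adjusted p = 0.069). The retinoic acid-degrading enzyme Cyp26a1 rose from 0.601 ± 0.135 to 7.42 ± 1.60 CPM (log2 fold change 3.60, SE 0.3), with Dhrs3 (1.65) higher and Crabp1 (-1.32, but -0.71 with adjusted p = 0.269 without wild-type replicate 2) lower. Of 42 axon guidance genes, 4 rose and 2 fell (6 and 2 when adjusted over the list alone, list adjusted p = 0.206), with Efna1 (1.08) and Robo4 (1.74) higher and Efnb3 (-1.01) and Epha3 (-2.98) lower.

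The matrix and adhesion list had 6 of 60 members higher and 5 lower (6 and 6 when adjusted over the list alone, list adjusted p = 0.665). Mixed fry called this list (adjusted p = 2.08e-07). Col3a1 fell by 1.63 on the log2 scale (SE 0.156, adjusted p = 0.000171) and Emid2, a collagen gene, by 2.23 (SE 0.308), while the inhibitor Timp3 (1.36, SE 0.153) and the syndecan Sdc4 (1.52, SE 0.199) rose.

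None of the 4 heart muscle and cardiac factor lists was called by camera, while mixed fry called all 4 (adjusted p = 4.74e-05 to 0.000936). Of 18 genes in the canal myocardium list, 2 rose (3 when adjusted over the list alone, list adjusted p = 0.998), Isl1 (1.77, SE 0.354) and Kcne1 (0.79, SE 0.211). Isl1 also stood in the cardiac factor and second heart field lists, and lost its call without wild-type replicate 2 (edgeR adjusted p = 0.0804). Kcne1 lost its call with any 1 library left out except null replicate 4 (edgeR adjusted p = 0.0515 to 0.212). Of 24 chamber myocardium genes, 2 rose and 3 fell (3 and 3 when adjusted over the list alone, list adjusted p = 0.665), and the ventricular genes Myl2 (-0.86), Irx4 (-0.71) and Irx5 (-1.34) were those lower. These 3 lost their calls without wild-type replicate 2 or 3 (edgeR adjusted p = 0.0597 to 0.211). Of 38 sarcomere and calcium genes, 2 rose and 1 fell (4 and 1 when adjusted over the list alone, list adjusted p = 0.492). Myh7 rose by 0.80 and Nebl by 0.64, and Pln, the inhibitor of the calcium pump, fell by 1.69 (SE 0.181), from 146 ± 35.5 to 45.4 ± 6.33 CPM. Of 29 cardiac transcription factors and partners, 2 rose and 2 fell (2 and 2 when adjusted over the list alone, list adjusted p = 0.998), with Isl1 among those higher and Hopx (-0.80) and Irx4 lower. Median, mean and test differed in sign for the canal myocardium, cardiac factor, Notch and WNT lists, whose medians lay between -0.06 and 0.02, and the medians of the Notch and WNT lists changed sign with the scaling.

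**Figure D3:**
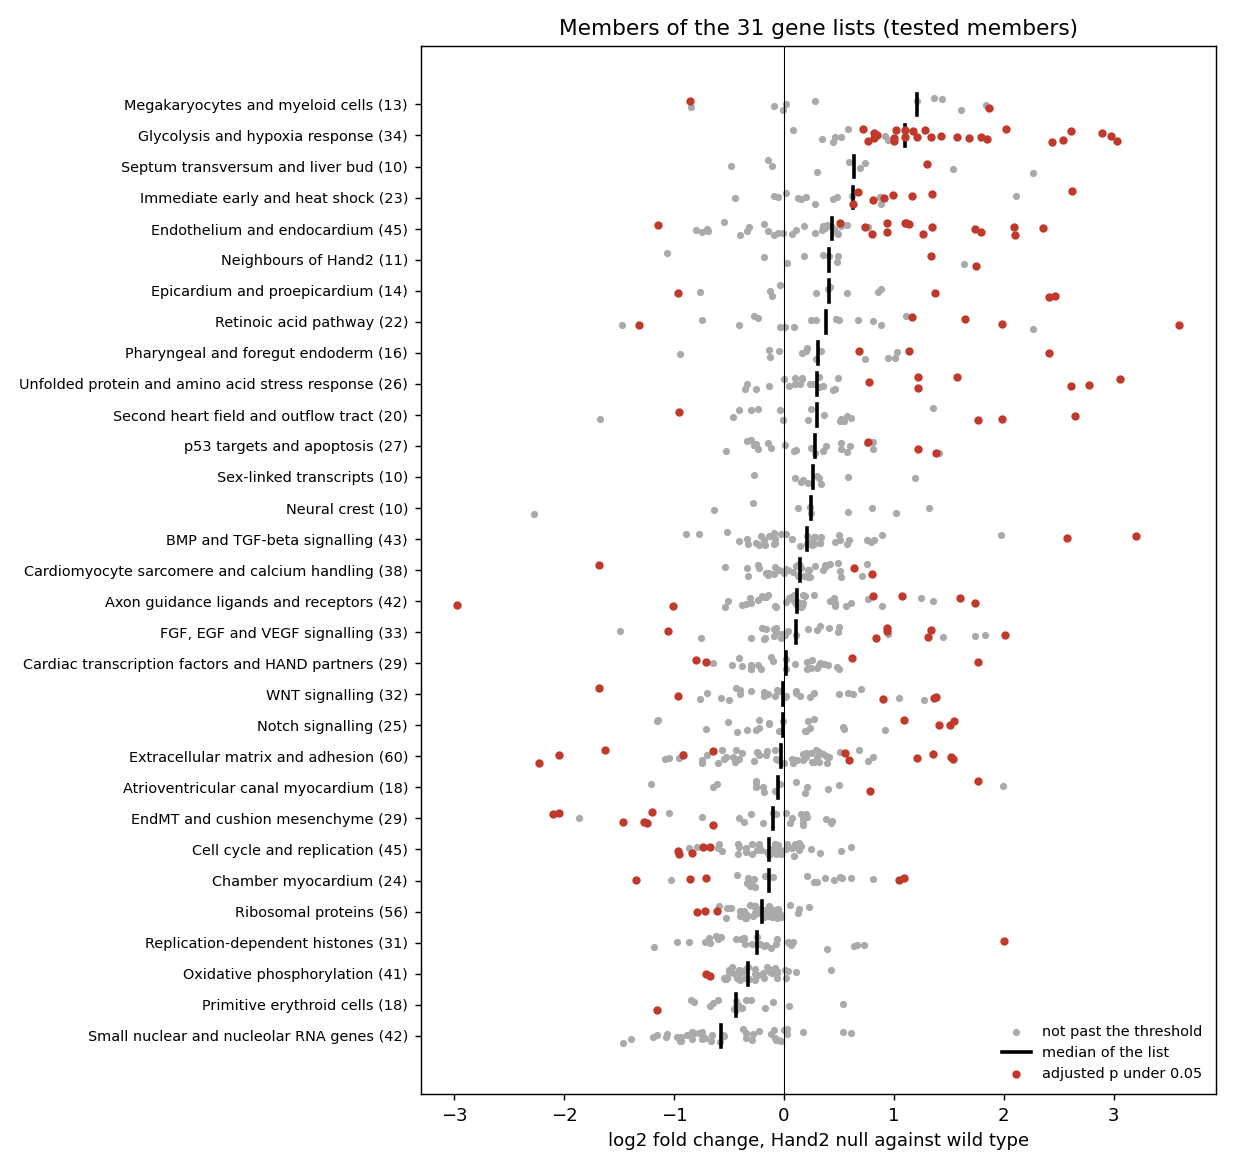
Log2 fold change of each tested member of the 31 lists, with called genes in red, other members in grey and the median of each list as a black bar, and the number of tested members in brackets. The glycolysis and hypoxia list had 26 called members, all to the right of 0, and the EndMT list had 7, all to the left.

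Markers of neighbouring tissues and of blood were measured because a dissected canal can hold them. Of 20 second heart field and outflow tract genes, 3 rose and 1 fell (3 and 1 when adjusted over the list alone, list adjusted p = 0.249), with Osr1 (2.65, SE 0.505, and 3.51 without wild-type replicate 3) higher and Ccnd2 (-0.96, SE 0.176) lower. Of 16 pharyngeal and foregut endoderm genes, 3 rose (3 when adjusted over the list alone, list adjusted p = 0.0941), which were the keratins Krt19 (2.41), Krt18 (1.14) and Krt8 (0.69). Of 14 epicardial genes, 3 rose and 1 fell (4 and 1 when adjusted over the list alone, list adjusted p = 0.104), including Fam70a (2.47, and 3.06 without wild-type replicate 3) and Gpm6a (1.38). Of 10 septum transversum and liver bud genes, Hhex rose (1.30; 2 when adjusted over the list alone, list adjusted p = 0.199). None of 10 neural crest genes was called by edgeR, DESeq2 or limma-voom, 0 had an unadjusted edgeR p under 0.05, and 0 were called when adjusted over the list alone (list adjusted p = 0.492), and the most abundant, Ednrb and Alx1, had 0.24 and 0.80. Of 18 erythroid genes, Klf1 fell (-1.16, SE 0.298; 3 when adjusted over the list alone), with an adjusted p of 0.0895 without null replicate 1, 0.0567 without null replicate 2, and 0.0551, 0.0895 and 0.117 without wild-type replicates 2, 3 and 4. The erythroid list was called lower (adjusted p = 0.0344), against an adjusted p of 0.774 with an estimated correlation, with a median of -0.43, which was -0.78 without null replicate 2 and -0.68 without wild-type replicate 2. Its adjusted p was 0.542 without wild-type replicate 4 (median 0.075), 0.0976 without null replicate 1 and 0.142 without null replicate 3. The erythroid call was also lost with the length offset (median -0.383, adjusted p = 0.0991) and with haemoglobin genes left out (-0.416, 0.0954). Haemoglobin reads were 0.870% ± 0.385 in the null and 1.46% ± 0.647 in wild type (SD, exact permutation p = 0.1714, n = 4 and 3). Of 13 megakaryocyte and myeloid genes, Mrc1 rose (1.86) and Lyz2 fell (-0.86; 2 and 1 when adjusted over the list alone, list adjusted p = 0.411). Leaving out libraries or another filter brought other tissue lists past the threshold. These were endoderm without null replicate 1 (adjusted p = 0.0186) or wild-type replicate 2 (0.0489), epicardium without null replicate 2 (0.0364) or 4 (0.0425), and septum transversum without null replicate 4 (0.049) or wild-type replicate 4 (0.0155). Without null replicate 2 and wild-type replicate 4 together, epicardium (0.0175) and septum transversum (0.033) passed, and with a stricter filter on low counts endoderm (0.0135) and epicardium (0.0485). The second heart field list passed without wild-type replicate 2 (0.0489) and the megakaryocyte and myeloid list without null replicate 1 (0.0437).

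Of 45 cell cycle genes, 5 fell and none rose (7 lower and 1 higher when adjusted over the list alone), among them Pcna (-0.67), Tk1 (-0.97), Tyms (-0.74) and the cyclin Ccnd2, with a camera adjusted p of 0.00161 and an adjusted p of 0.616 with an estimated correlation. Without null replicate 3 the list's median was -0.059 (adjusted p = 0.0658) and without null replicate 4 it was -0.25, against -0.13 with all libraries. Of 41 genes of oxidative phosphorylation, 2 fell, Cycs (-0.68) and Atp5g1 (-0.71), and 10 were lower when adjusted over the list alone. Cycs and Atp5g1 lost their calls without wild-type replicate 2 (edgeR adjusted p = 0.0698 and 0.101) or 3 (0.0962 and 0.113). The list median was -0.32 (camera adjusted p = 1.78e-06, adjusted p = 0.569 with an estimated correlation), and -0.094 with an offset for transcript length (adjusted p = 0.00995). Of 56 genes in the ribosomal list, 3 fell (3 when adjusted over the list alone), Rps19bp1 (-0.79), Rps27l (-0.61) and Rpl34 (-0.72), of which Rps19bp1 is not a ribosomal protein. All 3 lost their calls without null replicate 1 or 2, or wild-type replicate 2 or 3 (edgeR adjusted p = 0.0567 to 0.216). The list median was -0.20 (camera adjusted p = 0.000276, adjusted p = 0.774 with an estimated correlation). With the length offset, chosen after seeing the data, the ribosomal list was no longer called (adjusted p = 0.467). In the main test its median was -0.098 without null replicate 2, -0.12 without wild-type replicate 3 and -0.30 without wild-type replicate 4. Reads that aligned to several places, which are not counted, were 10.5% ± 1.11 in null and 13.1% ± 0.799 in wild-type libraries, without overlap (SD, exact permutation p = 0.0571, n = 4 and 3). Of 31 replication-dependent histone genes, Hist3h2ba rose (2.00; 1 when adjusted over the list alone, list adjusted p = 0.0941), and the list was called lower without null replicate 3 (adjusted p = 0.0238) or wild-type replicate 4 (0.0463), with no filter on low counts (0.0246) and with the erythroid covariate (0.00191). Of 42 tested small nuclear, nucleolar and other noncoding RNA genes, none was called by edgeR, DESeq2 or limma-voom. When adjusted over the list alone 0 were called, and 8 had an unadjusted edgeR p under 0.05. That list was called lower (median -0.57, adjusted p = 3.36e-05, and 0.381 with an estimated correlation). Its median was -0.37 without wild-type replicate 2. Its adjusted p was 0.884 with the length offset and 0.0849 with a stricter filter on low counts, and with no such filter at all its median was 0.056 (adjusted p = 0.19). In the main test its most abundant members Rn45s and Mir5109 had -0.12 (SE 0.429) and -0.09 (SE 0.362). Rn45s is the ribosomal RNA precursor and not a small RNA. None of the 10 sex-linked transcripts was called by edgeR, DESeq2 or limma-voom, 0 had an unadjusted edgeR p under 0.05, and 0 were called when adjusted over the list alone (list adjusted p = 0.316). The most abundant of these, Ddx3x and Eif2s3x, had -0.27 and 0.10.

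Variants near a targeted allele can be inherited with it, so genes near Hand2 were counted separately, by gene order and distance in GRCm38. Within 10 Mb, 8 of 39 tested genes were called (20.51%), against 6.23% of 14084 genes elsewhere (odds ratio 3.89, 95% interval 1.54 to 8.67, two-sided Fisher's exact p = 0.00249). The 8 include Hand2, whose call the deletion itself gives. Without Hand2, 7 of 38 were called (18.42%, odds ratio 3.4, 95% interval 1.26 to 7.9, Fisher's exact p = 0.00843). The others besides Hand2 were Hpgd, Gpm6a, Vegfc, Clcn3, Nek1, Tll1 and 2700029M09Rik, of which the last fell and the others rose. Hpgd, Gpm6a and Vegfc lost their calls without wild-type replicate 2 (edgeR adjusted p = 0.165, 0.0549 and 0.165). Clcn3, Nek1, Tll1 and 2700029M09Rik were named after their values were seen. With Hand2 counted, the odds ratio was 5.99 within 2 Mb (exact p = 0.0667), 1.59 within 20 Mb (exact p = 0.069) and 1.21 for the whole chromosome (exact p = 0.186). Within 2 Mb only 2 of 7 genes were called, Hand2 among them. Of 11 tested genes in the list of Hand2 neighbours, Hpgd (1.75, SE 0.454) and Vegfc (1.34, SE 0.361) rose (4 when adjusted over the list alone, list adjusted p = 0.0621). That list was called higher with any 1 library left out except null replicate 3 or wild-type replicate 4 (adjusted p = 0.00744 to 0.0426), with a stricter filter on low counts (0.0373) and with directional fry (0.00171).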

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

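The tests of the explanations in this part were chosen after the results they bear on had been seen, except the correlation of the glycolysis and immediate early scores, although the GC-content offset, the erythroid covariate and the fit without wild-type replicate 4 that some of them use had been planned. The rule for reading that correlation was changed after it was seen.

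Among 158 library measures, list scores and named genes, 6 had 1 null library far from the other 3 by Dixon's test, where chance gives about 7.9. Null replicate 2 had 57.9 CPM in olfactory and vomeronasal receptor genes, against 20.6 to 26.6 in the other null libraries. Null replicate 3 had an axon guidance score of 3.60, against 3.39 to 3.41. Null replicate 4 had 65.2 CPM of Eno2 (others 119 to 127) and 54.8 CPM of Pln (others 41.3 to 42.7). Null replicate 2 had 106 CPM of Kdr (others 84 to 87.1) and 1.55 CPM of Hist3h2ba (others 3.53 to 3.89).

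Chance assignment of libraries was weighed by splitting them in other ways. Of the 35 splits of the 7 libraries into 4 and 3, only the real 1 gave as many genes higher (587, highest other 0), and 1 as many lower (305, highest other 2). These counts argue against chance assignment but cannot exclude it, because 35 splits allow no p below 0.0286. Every other split also mixes the genotypes, which raises the variance within its groups and lowers its calls. For the number of lists called with a preset correlation, chance stays open. There, 24 of the 35 splits gave at least the 9 lists of the real split, and the highest other gave 15.

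The rise of the glycolysis and hypoxia list was weighed against 2 technical explanations. A lower share of blood cells is argued against, because the list median was 1.12 with the erythroid score as a covariate and 1.10 without it. Handling stress during dissection stays open: the deviations of this score and of the immediate early score from their genotype means had r = 0.55 (exact permutation p = 0.438 over 144 orders) and rho = 0.86 (exact p = 0.125) over 7 libraries. In wild-type libraries the 2 scores hardly varied (SD 0.04 and 0.02, against 0.24 and 0.25 in the null), so r rests mostly on the null pools. Without null replicates 3 and 2, farthest out in the immediate early score, r was 0.84. That value carries no weight, because the libraries were left out by 1 of the scores compared. The test cannot tell stress that was common to all null pools from an effect of genotype. A response of the mutant heart itself to low oxygen may contribute and was not tested.

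Of the endothelial list 15 of 45 members rose and 1 fell, while of the EndMT list 7 of 29 fell, 13 had positive values and the list was not called (adjusted p = 0.0754). A larger share of endothelial cells as the whole cause stays open. Endothelial members did not rise alike. Of the 45 tested, 55.6% had a 95% interval that excluded the list median of 0.44, with 12 above and 13 below it. With a larger share, members also expressed in other cells would rise less and lower the median. Members specific to endothelium would then lie above it, so this spread cannot decide the question. Whether 1 wild-type library rich in mesenchyme made the EndMT genes fall cannot be told, because the median of the 7 called members was -1.02 without wild-type replicate 4 and -1.27 with it, a difference within their standard errors, and these genes had been picked for their fall. An effect of genotype on the transition may underlie both and was not tested further.

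The fall of the oxidative phosphorylation and ribosomal lists could reflect transcript length, whose median was 1981 nt in called genes that were lower and 3730 nt in those higher. With a length offset the ribosomal median moved from -0.20 to -0.031 and the list was no longer called (adjusted p = 0.467), as a length bias would give. The offset would also take up a real fall shared by genes of similar length, so it cannot tell such a fall from a bias. The oxidative phosphorylation median moved from -0.32 to -0.094 but the list stayed called with the preset correlation (adjusted p = 0.00995), so length may explain part of it and the rest stays open. Without the offset the call was already lost with an estimated correlation (adjusted p = 0.569) and with directional fry (0.0548). GC content is argued against, with medians of -0.346 and -0.206 under its offset.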

How the results depend on the processing

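Hand2 kept its direction and call in every setting (log2 fold change -7.23 to -6.50), and no result changed direction past the threshold. The length offset, the fit without null replicate 2 and wild-type replicate 4, and the 3 counts of list members were chosen after seeing the data. The cause of the changes below was not tested. Higher and lower genes numbered 993 and 768 with DESeq2, where 9115 adjusted p were not given, 368 and 106 with the Y-linked covariate, 226 and 57 at an adjusted p under 0.01 (a stricter threshold), and 298 and 123 without null replicate 2 and wild-type replicate 4 together. With the erythroid covariate 669 genes were lower. Calls were 65.8% higher, but 56.4% with DESeq2, 77.6% with the Y-linked and 54.5% with the erythroid covariate. Whether replicate numbers pair the samples was not settled. Same-number deviations correlated by -0.07, 0.26 and 0.17 for numbers 2 to 4. Null and wild-type replicates 3 and 4 each correlated best with their own number, but both replicates 2 with number 4. With the replicate block, lower genes were 565 with all libraries, 578 with replicates 2 to 4, and 629 with the GC-content offset. The block also brought the FGF, EGF and VEGF list (adjusted p = 0.0183 with all libraries), the endoderm list (0.0114) and the histone list (0.0458) past the threshold, with the Hand2 neighbours over replicates 2 to 4 (0.0401) and the p53 list under the GC-content offset (0.042), and the erythroid list no longer passed (0.142). Leaving out 1 library gave 210 to 946 genes higher and 46 to 652 lower, 9 to 16 lists, 16 to 29 glycolysis members higher, 1 to 7 EndMT members lower and 9 to 16 endothelial members higher. EndMT members lower were 3 with the erythroid covariate and 1 without null replicate 2 and wild-type replicate 4, where 9 endothelial members were higher. Lists called were 0 with an estimated correlation (3 had an unadjusted p under 0.05), 6 with directional fry and 25 with mixed fry. The odds ratio near Hand2 was 5.99 within 2 Mb, 1.59 within 20 Mb, 1.21 for the chromosome and 3.4 within 10 Mb without Hand2. Of 97 called named genes, 45 lost the call with at least 1 library left out. In the simulation, 1.5-fold changes were recovered in 19.4% of genes. It gave 134 calls against 892 in the real data, where the adjusted threshold therefore admits larger p-values. The simulated share does not carry over, and how many small changes were missed is not known.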

Other observations

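The gene names in this part were chosen after their values were seen, and so were the tests. Some single genes of secreted peptides rose in the null, picked without a fixed list or a test of the group, while the natriuretic peptide genes Nppa and Nppb did not pass the threshold (adjusted p = 0.245 and 0.254). The apelin gene Apln rose by 3.16 (SE 0.505), the adrenomedullin genes Adm by 1.79 (SE 0.239) and Adm2 by 2.81 (SE 0.376), the stanniocalcin Stc1 by 2.18 (SE 0.236) and Calca, which encodes calcitonin and its related peptide, by 2.27 (SE 0.45) on the log2 scale. Adm is also a member of the glycolysis and hypoxia list. The metallothionein genes Mt1 (1.89, SE 0.333) and Mt2 (1.60, SE 0.429) rose as well. Ccl7, a chemokine like Ccl2, was at 0.0636 ± 0.0927 CPM in the null, a group mean below the floor, and at 3.04 ± 1.68 CPM in wild type (SD, n = 4 and 3). The imprinted genes Cdkn1c, a cell cycle inhibitor, and Phlda2 fell by 1.14 (SE 0.146) and 1.04 (SE 0.232).

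Genes were also grouped by the letters that open their symbols, for all 155 groups with at least 10 tested members. Of the genes of the large subunit of the mitochondrial ribosome (Mrpl), 7 of 47 fell and none rose (one-sided Fisher's exact adjusted p = 0.0176 over all groups and both directions). The test takes genes as independent, which members of a group may not be. Mrpl36 (-0.67, SE 0.117) and Mrpl20 (-0.72, SE 0.129) had the smallest p. The small subunit (Mrps) had 4 of 29 lower, with an adjusted p of 0.328, and no other group passed the threshold. Some groups that did not pass had a lower median log2 fold change than Mrpl (-0.39), such as Timm (-0.46) and Ndufb (-0.44). The length offset was not applied to this grouping.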
